A study of Danio rerio with 4 samples.

How the data were processed

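RNA from whole zebrafish larvae was sequenced in 4 libraries, 2 from untreated larvae and 2 from larvae exposed to PM2.5, and each library was placed in its group by its title. Per the labels' protocols, the larvae were exposed from 72 to 120 hours after fertilization, only RNA with an integrity number above 7.8 was sequenced, and paired-end reads of 150 bases were made. The labels name more than 1 RNA extraction kit and more than 1 sequencer model, and which was used is not settled here. Per the submitters' processing notes, the tools named are cutadapt 1.18 and STAR 2.6.1c, with the genome build GRCz11. The counting program, the gene annotation, the gene lengths, the strand setting and the treatment of reads that match several places are not given in the sources used here.

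The authors deposited 1 table of TPM (a read number divided by gene length and scaled so that each library has the same total). The table had 32925 rows, of which 405 repeated a gene ID already listed with the same TPM. Each of the 32520 distinct IDs was used once. Because every library is scaled to the same total, a TPM is a share, and a rise of some genes lowers the shares of the others. Gene symbols came from the table itself and, where a listed symbol was missing, from a reference table of gene names. Of 1344 list entries 1322 matched a gene ID, and 1223 were tested. No genome or transcript sequence was used, so no coordinates beyond the chromosome are printed, and the test of genes with a miR-192-5p seed site in their 3' untranslated region was not run.

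TPM keeps no depth, but a gene's values in different libraries are whole multiples of what 1 read is worth. With numbers up to 200000 and a tolerance of at most 0.02 reads, whole read numbers fitted all 25331 genes above 0 in at least 2 libraries. They hold at best up to a factor common to all libraries of a gene. So wide a search would find a fit for nearly any gene, so the share fitted is no evidence for the numbers. For genes with many reads a smaller number may have fitted by chance. On simulated counts for 3000 genes the step returned the exact read numbers for 92.3% of genes and the numbers up to a common factor for 99.9%. These read numbers gave an approximate depth between 12308987 and 19885004 reads per library. They were used for an alternative fit, with limma voom, chosen after seeing the data.

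Genes with a mean of at least 1 TPM over the 4 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (a linear model with the group as the only term, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The fold change is on the log2(TPM + 1) scale and understates the change of genes with low TPM. The model has 2 residual degrees of freedom per gene and gains 4.15 from the other genes. Gene lists were tested with limma's camera (preset correlation of 0.01, at least 5 tested members, Benjamini-Hochberg adjustment over lists). It asks whether a list's genes stand apart from all other tested genes, and its p rests on the spread across genes. Beside it, camera with an estimated correlation and fry were run. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, so a list could hardly pass. A call lost there does not argue against a list. The 41 gene lists, the tests, all alternatives but the voom fit and the rule for naming genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping groups and a usable symbol, then npnt, nphs1, podxl, wt1a, wt1b, mir192, cyp1a, hmox1a, mt2 and il1b whatever their values. It adds the 4 members with the smallest p in each list past the threshold and the 2 with the smallest p in each other list on the glomerulus, xenobiotic response, oxidative stress or inflammation. Among the genes past the threshold, 355 of the higher and 107 of the lower ones had no usable symbol and were counted only. Some genes that the rule takes are not reported here by name, but they enter the counts and list tests.

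The tests were tried on simulated data before use. In 20 simulated sets with 200 changed genes among 20874, the limma test recovered 3.08% of genes changed by 0.5 on the log2 scale, 25.5% of those changed by 1 and 72.9% of those changed by 2, and 5.03% of its calls were false. In that setting, with few changed genes, small true changes of single genes were mostly missed. The data had more genes past the threshold (2313), among them small changes such as 0.17 for rps27a. The simulated rates therefore do not carry over directly to the data. A list shifted by 0.5 was recovered by camera in 20 of 20 simulated sets, and 0% of unshifted lists were called. The simulated genes were drawn independently, whereas the estimated correlation in the data reached 0.41 (ribosomal proteins). The simulation therefore gives no rate of false calls for lists of correlated genes.

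The alternatives were a pseudocount of 0.1 or 5 TPM, no filter on low values beyond a TPM above 0 in 1 library, a minimum mean of 5 TPM, a trimmed-mean (TMM-type) rescaling of the libraries, quantile normalization, eBayes without the trend or with robust estimation, a fold threshold, the replicate number as a block, and each library left out in turn. Python 3.11.15 with numpy 2.4.6 was used for the read numbers and matplotlib 3.10.9 for the plots.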

Results

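Whole zebrafish larvae (Danio rerio) were profiled by RNA sequencing after exposure to PM2.5, the fraction of airborne smog particles small enough to be inhaled deeply, or without exposure. Exposed larvae received 12000000 particles from 72 to 120 hours after fertilization. The 2 groups, control and PM2.5, had 2 libraries each, and RNA came from 5 to 7 larvae per group. Each library was given in TPM, a gene's share of a library's transcripts, for 32520 distinct genes. The number of reads behind each library was worked out from the steps between its low TPM values. This approximate number came to 15717826 and 12308987 in the control libraries and to 19885004 and 12862435 in the PM2.5 libraries. PM2.5 library 1 was the deepest, yet it had the fewest genes above 0 (24121, against 25069 and 24923 in the controls and 25138 in PM2.5 library 2). It also had the most genes read only in the other 3 libraries: 171 genes with at least 20 reads there were at 0 in it, against 84, 75 and 35 in control 1, control 2 and PM2.5 library 2. The correlation of log2(TPM + 1) across genes, which are not independent replicates, was 0.979 between the controls, 0.969 between the exposed libraries and between 0.934 and 0.951 across groups. Nothing in the labels says that the libraries of a group came from separate clutches or exposures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. The camera p-values with the preset correlation rest on the spread across genes. They do not measure how larvae or libraries vary, however small they are.

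The series title names microRNA-192-5p and damage to the glomerulus, the filtering unit of the kidney, and the comparison asked which transcripts differed in larvae exposed to PM2.5. The gene that rose most on the log2(TPM + 1) scale was irg1l (ENSDARG00000062788, chromosome 14), which encodes an itaconate-producing enzyme of the innate immune response. It went from 2.08 ± 0.553 TPM in controls to 385 ± 8.61 TPM in exposed larvae (SD, n = 2), a log2 fold change of 6.98 with a standard error (SE) of 0.14. The inducible nitric oxide synthase gene nos2a (ENSDARG00000026925, chromosome 5) rose from 0.155 ± 0.135 to 31.0 ± 0.967 TPM, and mpeg1.2 (ENSDARG00000043093, chromosome 8), a perforin-like gene of macrophages, from 2.26 ± 1.66 to 78.0 ± 3.92 TPM. A keratin gene, krt96 (chromosome 22), rose from 3.93 ± 0.917 to 78.0 ± 2.82 TPM, and lygl1 (chromosome 14), a lysozyme g-like gene, from 5.51 ± 1.54 to 83.7 ± 3.43 TPM. The largest fall on that scale was in hamp (ENSDARG00000102175, chromosome 16), which encodes the iron hormone hepcidin: 21.1 ± 1.44 TPM in controls and 1.82 ± 0.188 TPM in exposed larvae, a log2 fold change of -2.97 (SE 0.16).

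The other genes with the largest rises were plekhs1 (log2 fold change 5.08), oxgr1a.1, an oxoglutarate receptor gene (3.93), the serine protease gene prss60.2 (3.70), the G protein subunit gene gna14 (3.58) and tmem176l.4 (3.56). Their adjusted p-values in the limma test ran from 6.6e-05 to 0.00064. Among the falls, the keratin gene cyt1l (chromosome 19) dropped from 771 ± 7.90 to 117 ± 0.362 TPM, with a log2 fold change of -2.71 and an adjusted p of 7.4e-06. The fatty acid binding protein gene fabp1b.2 (-2.46), the transcription factor gene fosab (-2.39), the fucosyltransferase gene fut9d (-2.14), the cytochrome P450 gene cyp2y3 (-1.96), the parathyroid hormone gene pth4 (-1.95) and pimr107 (-1.82) also fell. The symbol cyp2y3 here stands for ENSDARG00000068493, and reads shared with its relatives could not be separated. A pair of microRNA precursor genes completed the list. The gene dre-mir-24-3 was at 4.65 and 7.87 TPM in the controls and listed at 0 in both exposed libraries, and dre-mir-2188 at 3.63 and 3.58 TPM in the controls and listed at 0 in both exposed libraries. Such short rows rest on few reads.

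**Figure D1:**
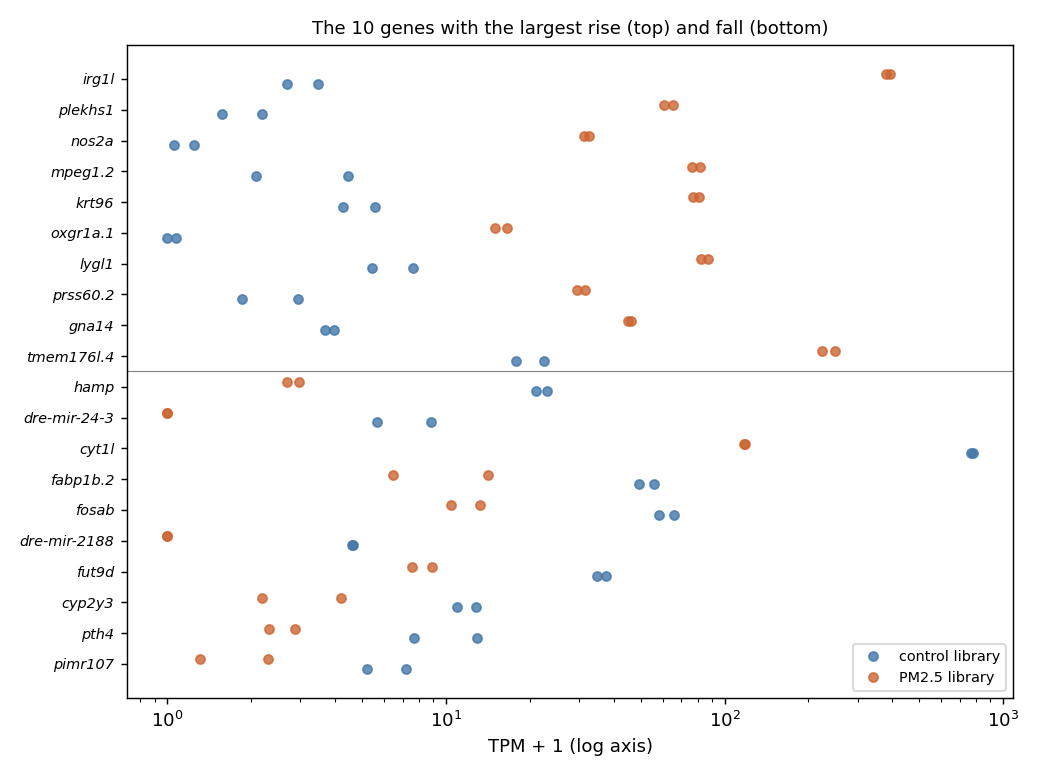
TPM + 1 on a log axis in each library, for the 10 genes with the largest rise (above the line) and the 10 with the largest fall (below it); blue points are control libraries and orange points PM2.5 libraries. For every gene drawn the points of the groups do not overlap, and irg1l lies at 391 and 379 TPM in the PM2.5 libraries against 1.69 and 2.48 TPM in the controls.

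Of 20874 genes tested, 1766 were higher and 547 lower in exposed larvae at an adjusted p under 0.05 (limma with an intensity trend on log2(TPM + 1), Benjamini-Hochberg adjustment), 2313 in all. At least 2-fold changes were seen in 675 of the higher and 104 of the lower genes. The counts of list members below are to be read against these 1766 and 547 of all 20874 tested genes. A few higher members of a list can match that background. An unadjusted p under 0.05 was found for 5669 genes. The values of the groups did not overlap in 56.3% of the tested genes, where chance gives 33.3% on average over the ways to split the libraries. Genes move together, so any factor shared within a group, technical ones included, could raise that share. The excess alone is therefore no evidence of an effect of exposure. Higher genes made up 76.4% of the calls with TPM as deposited, 59.9% after TMM-type rescaling and 57.9% after quantile normalization. Quantile normalization moved the median log2 fold change of all tested genes, which was 0.07 as deposited, by -0.11, so small changes below are read against that shift. With 2 libraries per group each one carried weight: the number of calls was 438 without control replicate 1, 534 without control replicate 2, 377 without PM2.5 replicate 1 and 857 without PM2.5 replicate 2. The 10 genes with the largest rise stayed past the threshold in all 4 of these fits, as did hamp, cyt1l, fosab and fut9d, while the other 6 of the 10 largest falls lost the call in at least 1 of them.

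Genes listed for the kidney filter showed few changes in the RNA of whole larvae. Such RNA carries no cell of origin, so the values of listed glomerular and basement membrane genes may come from other tissues. Some of these genes were low in controls: nphs1 at 0.430, wt1b at 1.92 and wt1a at 2.07 TPM. Of 43 tested genes of the glomerulus and its podocytes, the cells that hold the filtration slit, 3 rose and none fell with TPM as deposited (6 and 1 adjusted over the list alone). The genes that rose were myo1eb, a class I myosin gene (6.62 ± 0.0989 to 14.0 ± 0.285 TPM, log2 fold change 0.97), cd2ap, a slit diaphragm adaptor gene (13.0 ± 0.530 to 22.9 ± 1.67 TPM, 0.77), and ezrb, an ezrin gene picked after its values were seen (0.67). Their adjusted p-values were 0.0080, 0.012 and 0.013, and the calls of myo1eb and cd2ap were lost when any 1 of the 4 libraries was left out (adjusted p between 0.063 and 0.109). The list did not stand apart from other genes (camera adjusted p = 0.671, and 0.862 with an estimated correlation), and its median log2 fold change of 0.04 had the opposite sign to the camera direction. Calls of lower genes depended on scaling: after TMM-type rescaling and after quantile normalization 4 members, tjp1b, ptpro, robo2 and fat1a, were past the threshold as lower (named after their values were seen). Their log2 fold changes after TMM-type rescaling were -0.43, -0.33, -0.63 and -0.61.

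Individual glomerular genes fixed in advance did not pass. The gene for nephronectin, a basement membrane ligand whose gene is listed as npnta (ENSDARG00000018721, chromosome 1), was at 17.9 ± 0.333 TPM in controls and 16.0 ± 2.84 TPM in exposed larvae (log2 fold change -0.16, 95% confidence interval -0.51 to 0.20, adjusted p = 0.545), and its sign turned without PM2.5 replicate 1 (0.014). The podocalyxin gene podxl had a log2 fold change of 0.19 (-0.11 to 0.49), and the Wilms tumour genes wt1a and wt1b had 0.26 (-0.44 to 0.95) and -0.09 (-0.74 to 0.55). The nephrin gene nphs1 stayed under the minimum of 1 TPM, at 0.430 ± 0.0741 TPM in controls and 0.730 ± 0.141 TPM in exposed larvae, and was not tested. The precursor gene dre-mir-192 was listed at 0 in all 4 libraries, and these libraries give no measure of the mature microRNA.

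The 21 tested genes of the glomerular basement membrane included none past the threshold, over all genes or adjusted over the list alone. As a list they stood lower than other genes (median log2 fold change -0.14, camera adjusted p = 0.018), and the call was lost with an estimated correlation (adjusted p = 0.488). The members with the smallest p were the laminin genes lamc1 (-0.34, adjusted p = 0.097) and lamb2 (-0.26) and the heparan sulfate proteoglycan genes hspg2 (-0.50) and agrn (-0.30). After TMM-type rescaling lamc1 passed as lower (-0.43, adjusted p = 0.036). Of 36 tested genes of the pronephric tubule, 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.992).

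**Figure D2:**
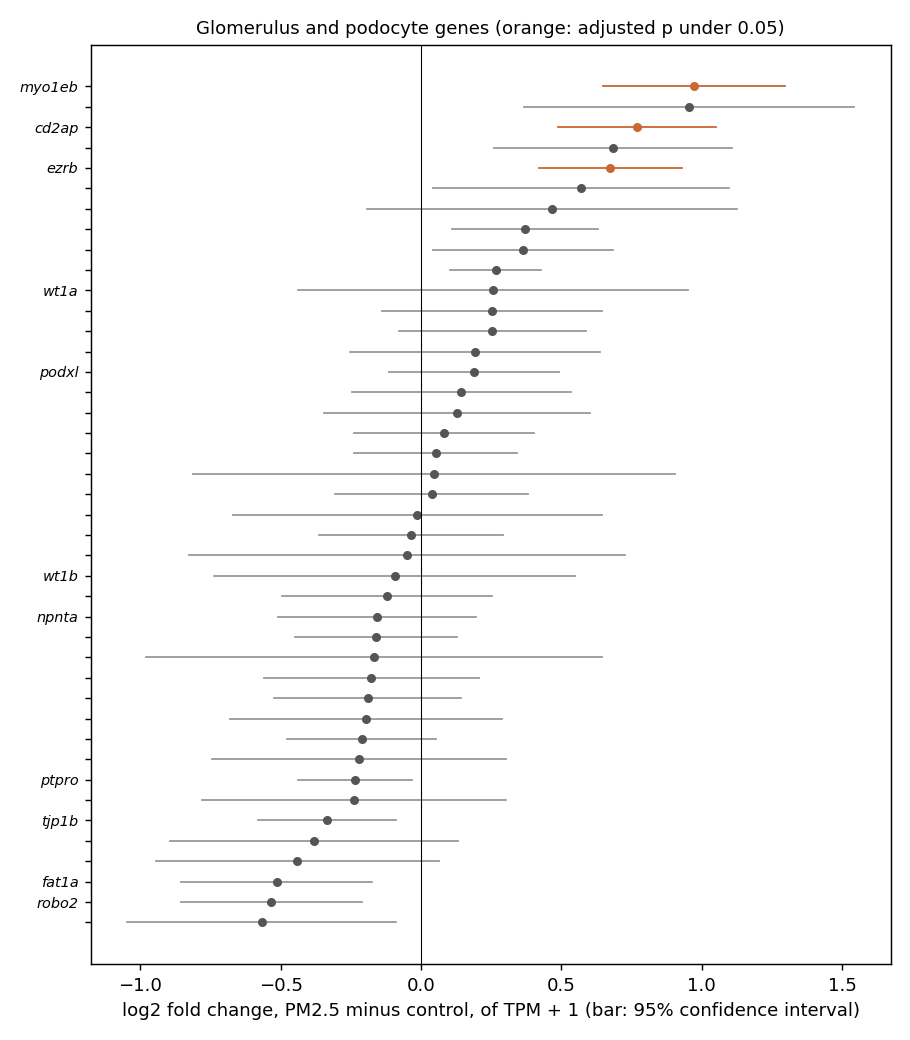
Log2 fold change of TPM + 1, PM2.5 minus control, for 42 of the 43 tested glomerulus and podocyte genes, with the genes named in the text labelled, each with its 95% confidence interval from limma (n = 2 libraries per group); orange marks an adjusted p under 0.05. With TPM as deposited 3 genes lie to the right with that mark and none to the left, while 4 of the genes on the left pass after rescaling.

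Part of the innate immune transcripts rose. In the list of inflammation and NF-kB genes 8 of 24 tested members rose and none fell with TPM as deposited (12 and 2 adjusted over the list alone), with a camera adjusted p of 0.0030, lost with an estimated correlation (adjusted p = 0.334). After TMM-type rescaling 1 member was past the threshold as lower, and after quantile normalization 2. Besides irg1l and nos2a, the rises included the NF-kB inhibitor gene nfkbie (5.94 ± 0.802 to 24.3 ± 0.579 TPM) and the cytokine signalling suppressor gene socs3b (22.3 ± 1.49 to 50.9 ± 5.56 TPM). The call of socs3b was lost without control replicate 1 (adjusted p = 0.051) and without PM2.5 replicate 1 (0.050). The interleukin-1 gene il1b was at 1.69 ± 0.0352 and 2.34 ± 0.163 TPM (log2 fold change 0.31, adjusted p = 0.476). Macrophage and microglia markers rose in 8 of 23 tested members and fell in none (8 and 0 adjusted over the list alone). The camera adjusted p was 0.00011, and 0.334 with an estimated correlation. The protease gene ctss2.2 rose from 6.71 ± 1.09 to 56.4 ± 3.45 TPM, the granulin gene grn2 from 7.75 ± 2.27 to 56.3 ± 4.84 TPM and the apolipoprotein gene apoeb from 490 ± 1.06 to 769 ± 14.7 TPM. The colony-stimulating factor receptor gene csf1ra, named after its value was seen, had a log2 fold change of 0.05 (adjusted p = 0.899).

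Neutrophil markers rose in 3 of 18 tested members (4 up and 1 down adjusted over the list alone): the NADPH oxidase genes cyba (12.7 ± 4.29 to 67.0 ± 0.738 TPM) and ncf1 (4.17 ± 1.52 to 12.3 ± 0.202 TPM) and the myeloperoxidase gene mpx (5.20 ± 0.895 to 10.8 ± 1.70 TPM). The matrix protease gene mmp9 had a log2 fold change of -0.54 (adjusted p = 0.051) and passed as lower after both rescalings. The neutrophil list had a camera adjusted p of 0.041, which was 0.336 with an estimated correlation, 0.156 with a mean of at least 5 TPM, 0.063 without PM2.5 replicate 1 and 0.056 without PM2.5 replicate 2. None of its 3 named genes past the threshold kept the call in all 4 fits that left out 1 library. Of 16 tested interferon response genes 2 rose, the regulator gene irf1a (1.39 ± 0.110 to 13.5 ± 0.793 TPM) and the antiviral gene mxc (1.35 ± 0.0421 to 4.52 ± 1.03 TPM), and 4 rose adjusted over the list alone. The call of mxc was lost without any 1 of the 4 libraries (adjusted p between 0.066 and 0.178). The log2 fold changes of irf1b (0.79, adjusted p = 0.052) and mxa (1.24, adjusted p = 0.081) did not pass. That list's camera adjusted p of 0.048 became 0.336 with an estimated correlation, 0.480 with a mean of at least 5 TPM, 0.053 with a pseudocount of 0.1 TPM, 0.088 without PM2.5 replicate 1 and 0.166 without PM2.5 replicate 2.

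Genes of protein folding in the endoplasmic reticulum and of protein degradation rose. In the unfolded protein response list 14 of 24 tested members rose and 1 fell (17 and 1 adjusted over the list alone; camera adjusted p = 1.0e-08, 0.216 with an estimated correlation). The chaperone genes hsp90b1 and hspa5 rose from 49.8 ± 1.74 to 160.4 ± 4.38 TPM and from 74.3 ± 2.38 to 215 ± 6.48 TPM, and the disulfide isomerase genes pdia4 and pdia3 from 12.1 ± 1.19 to 45.5 ± 1.96 TPM and from 139.7 ± 5.21 to 280.0 ± 0.222 TPM. These 4 kept their calls in all 4 fits that left out 1 library. The member that fell was the transcription factor gene atf4b (-0.32), named after its value was seen. Of 34 proteasome subunit genes 28 rose and none fell (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 3.4e-16, 0.216 with an estimated correlation). The rises of psmb1, psma8, psmd13 and psma4 were 0.71, 0.73, 0.74 and 0.67. The number of proteasome genes higher was 18 after TMM-type rescaling and 19 after quantile normalization.

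Among 31 tested genes of the oxidative stress response and its regulator Nrf2, 12 rose and 1, the glutathione peroxidase gene gpx4a, named after its value was seen, fell (16 and 3 adjusted over the list alone). The camera adjusted p was 0.0021, and 0.325 with an estimated correlation. The rises numbered 8 after TMM-type rescaling and 10 after quantile normalization. The quinone reductase gene nqo1 rose from 27.2 ± 1.49 to 69.5 ± 3.04 TPM, the peroxiredoxin gene prdx1 from 13.2 ± 0.724 to 29.6 ± 0.257 TPM and the glutathione transferase gene mgst3b from 138.6 ± 0.30 to 202 ± 2.38 TPM. Only nqo1 of these 3 kept its call in every fit that left out 1 library. The heme oxygenase gene hmox1a was lower in exposed larvae, at 13.3 ± 1.46 against 6.71 ± 2.16 TPM, without passing (log2 fold change -0.91, adjusted p = 0.051), and the metallothionein gene mt2 had a log2 fold change of 0.05 (adjusted p = 0.653). The aryl hydrocarbon receptor list of xenobiotic response genes did not stand apart (2 of 15 tested members higher and 1 lower; 3 and 2 adjusted over the list alone; camera adjusted p = 0.301, 0.487 with an estimated correlation). Within it cyp1a, the monooxygenase gene induced through that receptor, fell from 25.7 ± 0.0102 to 11.8 ± 0.607 TPM (log2 fold change -1.06, SE 0.11, adjusted p = 0.0030). The call was lost without control replicate 1 (adjusted p = 0.068) and without control replicate 2 (0.058).

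Transcripts of several differentiated tissues fell. Of 41 skeletal muscle genes 29 fell and none rose (35 and 0 adjusted over the list alone; median log2 fold change -0.32, camera adjusted p = 2.0e-27, 0.216 with an estimated correlation). The skeletal actin gene acta1a fell from 594 ± 13.5 to 362 ± 2.16 TPM, the calcium pump gene atp2a1 from 3949 ± 81.9 to 2949 ± 34.3 TPM, the calsequestrin gene casq1a from 212 ± 11.2 to 109 ± 5.14 TPM and the sarcomere gene tcap from 69.6 ± 6.13 to 27.7 ± 0.141 TPM. Of 28 tested lens crystallin genes 21 fell and none rose (24 and 0 adjusted over the list alone; median -0.49, camera adjusted p = 5.2e-24, 0.216 with an estimated correlation). Among them were crybb1 (3567 ± 22.4 to 2155 ± 1.90 TPM), crybb1l1 (-0.72), cryba1b (-0.58) and cryba1l1 (-0.54). Of 22 tested exocrine pancreas genes 10 fell and none rose (15 fell and 1 rose adjusted over the list alone; median -0.49, camera adjusted p = 3.1e-12, 0.216 with an estimated correlation). The trypsin genes prss1, prss59.1 and prss59.2 had log2 fold changes of -0.50, -0.65 and -0.60 and the elastase gene ela2l -0.48. Trypsin and crystallin genes have close copies, among which the authors' counting may have divided reads.

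Photoreceptor genes fell in 15 and rose in 3 of 46 tested members (19 and 5 adjusted over the list alone; camera adjusted p = 1.3e-08, 0.261 with an estimated correlation). The rises numbered 1 after either rescaling, with 16 lower by the TMM-type and 19 by the quantile method. Rhodopsin, rho, fell from 3466 ± 58.4 to 2301 ± 41.7 TPM, and pde6ha, rbp3 and gnat1 of the visual cycle and cascade had log2 fold changes of -0.48, -0.54 and -0.55. The call of gnat1 was lost without control replicate 1 (adjusted p = 0.068) and without PM2.5 replicate 1 (0.060). In the list of neuron and synapse genes 5 of 38 fell and 1 rose, in both counts (camera adjusted p = 8.0e-06, 0.457 with an estimated correlation). The falls numbered 7 after TMM-type rescaling and 9 after quantile normalization. The vesicle genes vamp2 (-0.54) and syn2b (-0.51) and the neurofilament gene nefla (-0.70) fell, and the glutamate receptor gene grin1b (0.35) rose with TPM as deposited but did not pass after either rescaling. Of 34 tested hepatocyte genes 9 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00023, 0.256 with an estimated correlation), 10 and 1 after TMM-type rescaling and 9 and 2 after quantile normalization. The secreted protein genes ahsg1 (23.6 ± 0.322 to 7.59 ± 0.202 TPM) and fetub (830 ± 55.6 to 538 ± 7.45 TPM) and the drug-metabolising gene cyp3a65 (445 ± 2.49 to 250.1 ± 1.17 TPM) fell, and the vitamin D binding protein gene gc rose from 722 ± 13.9 to 1131 ± 5.15 TPM. The call of fetub was lost without PM2.5 replicate 1 (adjusted p = 0.055).

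Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, fell in 8 and rose in 3 of 28 members (11 and 6 adjusted over the list alone; camera adjusted p = 0.0021, 0.325 with an estimated correlation). After TMM-type rescaling 9 were lower and 1 higher, and after quantile normalization 11 and 1. The fall was from 117.5 ± 5.28 to 38 ± 1.86 TPM for egr1, 131 ± 1.87 to 52.3 ± 3.57 TPM for junbb, 61.1 ± 5.45 to 10.9 ± 2.02 TPM for fosab and 77.0 ± 2.96 to 34.4 ± 0.517 TPM for ier2a, and all 4 calls held without any 1 library. Glucocorticoid and fasting genes fell in 7 and rose in 2 of 29 members (10 and 5 adjusted over the list alone; camera adjusted p = 0.00027, 0.339 with an estimated correlation), 9 and 1 after TMM-type rescaling and 10 and 2 after quantile normalization. The gluconeogenic genes pck1 (-0.45) and g6pca.2 (-0.73) and the growth factor binding protein gene igfbp1a (-0.42) fell, and the transcription factor gene cebpb (0.43) rose. Hypoxia and glycolysis genes fell in 6 and rose in 1 of 35 members (11 and 1 adjusted over the list alone; camera adjusted p = 0.00071, 0.260 with an estimated correlation). The counts became 9 lower and 0 higher after TMM-type rescaling and 10 and 1 after quantile normalization. The falls included gapdh (-0.32), aldoab (-0.31), pkmb (-0.41) and igfbp1a. None of the 4 genes named from the glucocorticoid list, nor of the 4 from the glycolysis list, kept its call in all 4 fits that left out 1 library. Muscle is a main source of several of these glycolytic transcripts, and gapdh is in the muscle list too.

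**Figure D3:**
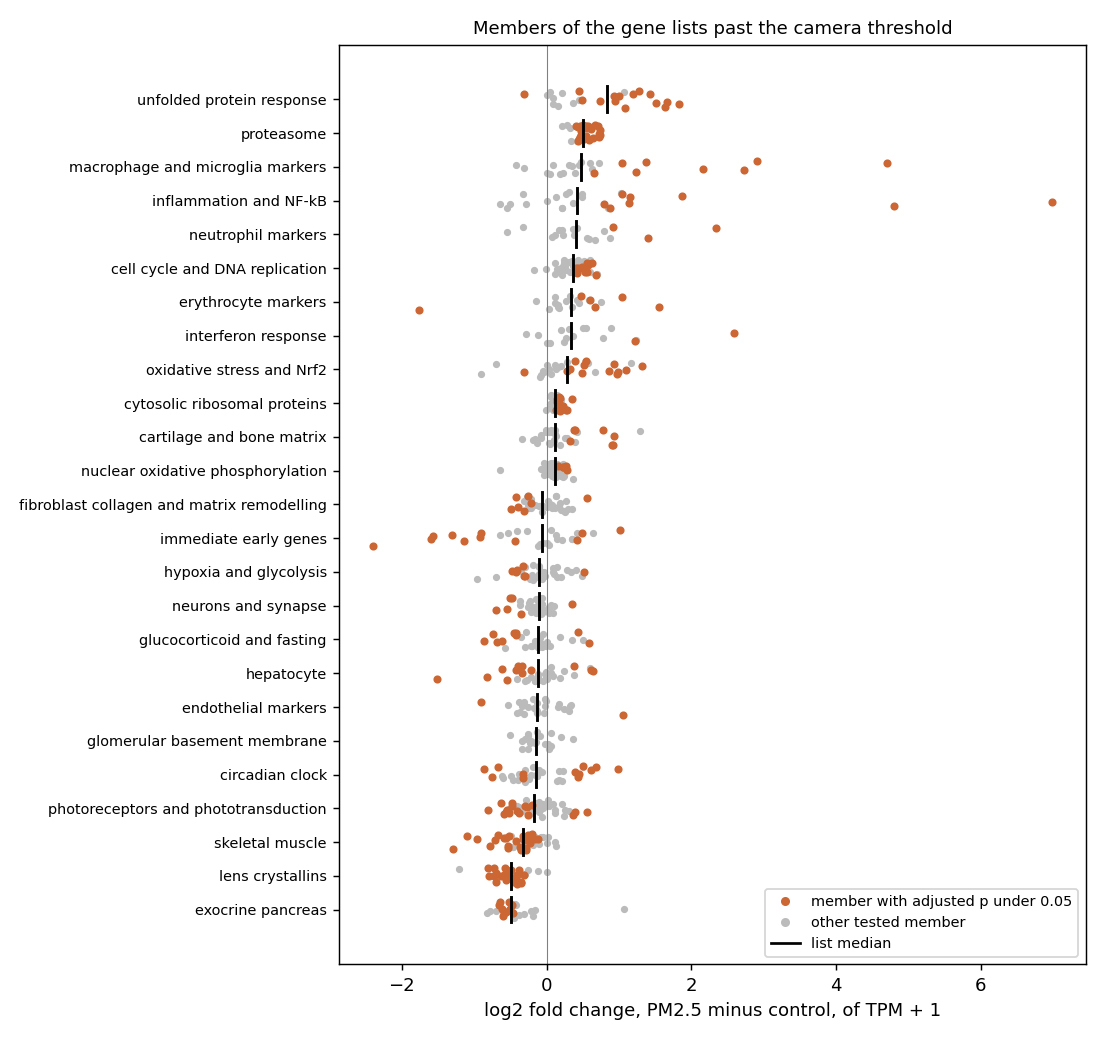
Log2 fold change of TPM + 1, PM2.5 minus control, of each tested member of the 25 gene lists past the camera threshold with a preset correlation; orange points have an adjusted p under 0.05, grey points do not, and the black bar is the list median. The medians run from -0.49 (exocrine pancreas) to 0.84 (unfolded protein response). No list keeps its call with an estimated correlation, a test with 2 residual degrees of freedom that could hardly pass any list.

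Cell cycle and DNA replication genes rose in 11 of 42 members and fell in none (20 and 0 adjusted over the list alone; median 0.36, camera adjusted p = 7.6e-07, 0.216 with an estimated correlation). The replication gene pcna was at 156.8 ± 1.54 TPM in controls and 211 ± 8.38 TPM in exposed larvae, and cdk1, mcm2 and rrm2 rose by 0.68, 0.64 and 0.55. After TMM-type rescaling 2 of these members were past the threshold (median 0.28, camera adjusted p = 2.4e-06) and after quantile normalization 3 (median 0.25, camera adjusted p = 1.6e-06). Cytosolic ribosomal protein genes rose in 13 of 70 members (38 adjusted over the list alone; median 0.12, camera adjusted p = 1.4e-10, 0.424 with an estimated correlation). Among them were rplp1 (0.35), rps20 (0.18), rps15 (0.22) and rps27a (0.17). The number was 0 after TMM-type rescaling, where the camera adjusted p was 0.316, and 44 after quantile normalization. Nuclear genes of oxidative phosphorylation rose in 5 of 48 members in both counts, including atp5f1c (0.22), atp5pd (0.27), atp5mc1 (0.23) and ndufa4 (0.29), and none of the members passed after TMM-type rescaling. The camera adjusted p of 0.018 became 0.382 with an estimated correlation, 0.781 after TMM-type rescaling, 0.073 after quantile normalization and 0.245 without control replicate 2. Leaving out 1 library at a time, none of the 4 genes named from each of these 3 lists kept its call throughout.

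Blood, vessel and matrix genes moved in both directions. Erythrocyte genes rose in 5 and fell in 1 of 20 tested members (8 and 1 adjusted over the list alone; camera adjusted p = 0.0042, 0.312 with an estimated correlation). The embryonic beta globin gene hbbe1.1 fell from 600 ± 21.4 to 176 ± 2.16 TPM, whereas hbbe1.2 rose from 69.1 ± 9.16 to 203 ± 13.2 TPM, hbbe1.3 from 115.6 ± 9.22 to 240.5 ± 24.1 TPM and the alpha globin gene hbae3 from 461 ± 17.4 to 644 ± 39.5 TPM. The 3 beta globin genes are near copies of each other, so reads may have been divided among them. The call of hbae3 was lost after TMM-type rescaling (adjusted p = 0.056), without control replicate 1 (0.058), without control replicate 2 (0.068) and without PM2.5 replicate 1 (0.064). Of 28 tested endothelial genes lyve1a fell (24.1 ± 0.865 to 12.5 ± 2.47 TPM) and sox7 rose (2.39 ± 0.391 to 6.04 ± 0.261 TPM), in both counts, and egfl7 (-0.53) and sox18 (-0.36) did not pass. Their list had a camera adjusted p of 0.023, which was 0.336 with an estimated correlation, 0.052 without control replicate 1 and 0.082 without PM2.5 replicate 2.

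Cartilage and bone matrix genes rose in 7 of 31 tested members and fell in none with TPM as deposited (9 and 1 adjusted over the list alone), while 1 was lower after TMM-type rescaling and 2 after quantile normalization. The matrilin gene matn3a rose from 65.2 ± 4.72 to 123 ± 1.98 TPM, col9a1b from 79.5 ± 9.0 to 136.7 ± 1.02 TPM, and sox9b and col2a1a by 0.92 and 0.32. The call of col2a1a was lost after TMM-type rescaling (adjusted p = 0.130). The list's camera adjusted p of 0.047 became 0.336 with an estimated correlation, 0.110 with a mean of at least 5 TPM, 0.165 after TMM-type rescaling, 0.135 after quantile normalization, 0.091 without control replicate 2, 0.099 without PM2.5 replicate 1 and 0.057 without PM2.5 replicate 2. Genes of fibroblast collagen and matrix remodelling fell in 6 and rose in 1 of 36 tested members (7 and 1 adjusted over the list alone; camera adjusted p = 0.013, 0.382 with an estimated correlation), and the falls numbered 7 after TMM-type rescaling and 10 after quantile normalization. The type I collagen genes col1a1b, col1a2 and col1a1a had log2 fold changes of -0.49, -0.31 and -0.21, and the growth factor gene ccn2a one of 0.56. Circadian clock genes rose in 7 and fell in 5 of 37 members with TPM as deposited (10 and 10 adjusted over the list alone). After TMM-type rescaling 5 were higher and 9 lower, and after quantile normalization 5 and 10. With TPM as deposited nr1d1 (66.2 ± 1.40 to 132.7 ± 4.36 TPM), bhlhe40 (0.50), cry3a (0.45) and nfil3 (0.68) all rose although the list as a whole stood lower than other genes. The camera adjusted p of the clock list was 0.037, which was 0.687 with an estimated correlation, 0.081 with a mean of at least 5 TPM, 0.094 without control replicate 2 and 0.063 without PM2.5 replicate 1.

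In all, 25 of the 41 lists passed the camera test with the preset correlation, 12 higher and 13 lower. None passed with an estimated correlation, where 7 had an unadjusted p under 0.05 and the smallest adjusted p was 0.216. With 2 residual degrees of freedom that test could hardly pass any list. By fry, which asks whether a list's genes move one way without comparing them with other genes, 20 lists passed. Of the 25, the clock, ribosomal protein, endothelial, fibroblast, basement membrane, glucocorticoid, neuron and oxidative phosphorylation lists did not (adjusted p between 0.071 and 0.560). The heat shock, p53 and epidermis lists passed by fry (adjusted p = 0.032, 0.024 and 0.022) but not by camera. Leaving out 1 library at a time, 19 of the 25 stayed past the threshold in all 4 fits. Of the 4 genes named per list, 1 kept its call throughout for each of the exocrine pancreas, clock, cartilage and fibroblast lists, 2 for the proteasome and none for neurons. Of the 2 past the threshold, none did for the endothelial list and 1 for the interferon list.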

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

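All 126 tested genes taken by the naming rule and all 41 lists were refitted under the alternatives, of which the voom fit on whole read numbers was chosen after seeing the data. None of the 109 named genes and none of the 25 lists past the threshold changed direction in any alternative run. For the genes most runs could not have turned a sign, since the groups did not overlap in any of the 2313 called genes. Only TMM-type rescaling, quantile normalization and the voom fit could have done so. Leaving out 1 library at a time gave between 377 and 857 genes in all, between 288 and 611 higher and between 77 and 246 lower. Of the 109 named genes 50 kept their call in all 4 of these fits, and the call was lost for 49 without control replicate 1, 45 without control replicate 2, 53 without PM2.5 replicate 1 and 33 without PM2.5 replicate 2. In these fits the lone library of a group is assumed to vary like the other group, and fewer samples leave fewer calls. Without the intensity trend 770 genes passed (665 higher, 105 lower), of which 739 were among the 2313, and the cause was not tested. Requiring an absolute log2 fold change of at least 1 as well left 779 genes (675 higher, 104 lower) by construction. Quantile normalization raised the lower genes from 547 to 962, 1797 of its 2286 calls were among the 2313, and the cause was not tested. The voom fit gave 3708 genes, 1337 of them lower, shared 2132 with the 2313, and the cause was not tested. The other pseudocounts, TPM filters, TMM-type rescaling and robust estimation gave between 1750 and 2498 genes. Of the lists, 0 passed camera with an estimated correlation (0 higher, 0 lower; 7 at an unadjusted p under 0.05), against 25 with the preset correlation. By fry 20 passed, 7 of them lower against 13, and the cause was not tested. A larger correlation between genes cannot account for every lost camera call. For the exocrine pancreas, hepatocyte, erythrocyte, neutrophil and cartilage lists the estimated correlation lay below the preset 0.01 (-0.026, -0.012, -0.041, -0.034 and -0.033). For others it lay above, such as 0.41 for ribosomal proteins. With an estimated correlation camera takes its p from the 2 residual degrees of freedom, and with the preset from the number of genes. That change weakens every list test, including those of lists with a lower correlation. Calls lost there are thus no evidence against a list.

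Replicate numbers are shared between the groups, but no label says what they mark. Deviations of same-numbered libraries from their group means correlated at 0.065 across genes. With the replicate number as a block 2853 genes (2072 higher, 781 lower) and 24 lists (11 higher, 13 lower) passed.

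Reversals were seen for 4 named genes and 9 lists, all short of the threshold in the planned fit, and their cause was not tested. After TMM-type rescaling the log2 fold change of mt2 was -0.051. Over the fits without 1 library it ran from -0.016 to 0.11 for mt2, from -0.33 to 0.014 for npnta, from -0.0035 to 0.51 for wt1a and from -0.20 to 0.017 for wt1b. For lists, the adjusted p with the opposite direction was 0.813 for fatty acid oxidation with no filter on low values and 0.972 with the replicate block. With a mean of at least 5 TPM it was 0.588 for the pronephric tubule, 0.98 for yolk and lipoprotein and 0.748 for hair cells. After TMM-type rescaling it was 0.958 for the pronephric tubule and 0.347 for mitochondrially encoded transcripts. After quantile normalization it was 0.926 for the pronephric tubule, 0.999 for the intestine and 0.806 for yolk and lipoprotein. In the voom fit it was 0.967 for the pronephric tubule and for yolk and lipoprotein. By fry, which makes no comparison with other genes, it was 0.740 for the aryl hydrocarbon receptor list, 0.244 for the glomerulus, 0.162 for the intestine, 0.169 for yolk and lipoprotein, 0.177 for fatty acid oxidation, 0.516 for glia and myelin and 0.474 for hair cells. Over the fits without 1 library, in 1 or more of which the direction turned, the adjusted p ran from 0.665 to 0.909 for the pronephric tubule, from 0.220 to 0.928 for the intestine, from 0.774 to 0.998 for yolk and lipoprotein and from 0.576 to 0.934 for fatty acid oxidation.

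The planned test of miR-192-5p seed sites and its alternatives were not run, since they need 3' untranslated sequences. Depth limits genes of low TPM most, nphs1 among those named.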

Other observations

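The tests of explanations in the last 3 paragraphs were all chosen after the results were seen, and genes not named before were picked after their values were seen. Epidermal genes moved strongly both ways, so that their list did not stand apart. Of 36 genes of epidermis and ionocytes 11 rose and 6 fell (18 and 8 adjusted over the list alone; camera adjusted p = 0.296). The keratin genes cyt1 (log2 fold change -1.54), krt4 (-1.34), krt5 (-0.93) and krt97 (-0.89) fell. The keratin gene krt96 (4.01), the annexin gene anxa1b (2.38), the claudin gene cldne (1.96) and the ionocyte genes rhcga (1.82) and trpv6 (1.33) rose. Iron genes split too, with 6 of 21 metal and iron genes higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.799). Beside the fall of hamp, the ferritin genes fthl28 (1.61) and fthl30 (1.57) and the transferrin receptor gene tfr1b (0.65) rose. Of 20 heat shock and folding genes 9 rose and 3 fell (11 and 3 adjusted over the list alone). After TMM-type rescaling 3 were higher and 3 lower, and after quantile normalization 5 and 2. The camera adjusted p of 0.070 passed as 0.041 after quantile normalization, 0.015 with a mean of at least 5 TPM and 0.037 without control replicate 1. The inducible genes hsp70l (-1.55) and hsp70.1 (-1.25) fell, whereas hsp90aa1.2 (1.07) and hspa4a (1.03) rose. Intestinal genes rose in 8 and fell in 6 of 32 members (8 and 7 adjusted over the list alone; camera adjusted p = 0.679), from the peptide transporter gene slc15a1b (-1.07) to the mucin-folding gene agr2 (2.85). After TMM-type rescaling 4 were higher and 7 lower, and after quantile normalization 7 and 7.

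Complement and acute phase genes rose in 3 and fell in 4 of 28 members (7 and 7 adjusted over the list alone; camera adjusted p = 0.085), with c4b (1.27) among the rises and c7b (-0.92) among the falls. That list passed as lower with a mean of at least 5 TPM (0.045) and without PM2.5 replicate 1 (0.016). In the list of p53 and DNA damage genes 4 of 30 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.619), and the caspase genes casp3b (1.76) and casp8 (1.43) were among the rises. After quantile normalization 3 of these members were higher and 3 lower. Fatty acid synthesis and storage had 3 genes higher and 3 lower of 25 with TPM as deposited (4 and 4 adjusted over the list alone; camera adjusted p = 0.088), 2 and 4 after TMM-type rescaling and 2 and 5 after quantile normalization. Fatty acid oxidation had 2 higher and 3 lower of 29 (3 and 4 adjusted over the list alone; camera adjusted p = 0.966), with the pyruvate dehydrogenase kinase gene pdk2b at -1.28, and 0 higher and 4 lower after either rescaling. Sterol synthesis had 3 higher and 1 lower of 24 (4 and 1 adjusted over the list alone; camera adjusted p = 0.525), and yolk and lipoprotein 4 and 1 of 19 (5 and 2 adjusted over the list alone; camera adjusted p = 0.991), or 2 and 1 after TMM-type rescaling. Glia and myelin had 1 gene higher and 2 lower of 25 (2 and 2 adjusted over the list alone; camera adjusted p = 0.525). Hair cells had 3 and 1 of 19 in both counts (camera adjusted p = 0.552). None of the 13 mitochondrially encoded transcripts passed in either count (camera adjusted p = 0.671), although the list passed as higher after quantile normalization (0.0064). For glia and myelin and for fatty acid oxidation the list median had the opposite sign to the camera direction. In both control libraries 16 genes were listed at 0 that had at least 2 TPM in both exposed libraries, 7 of them protein-coding, and the reverse held for 6 genes, of which 0 were protein-coding.

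Skeletal muscle, lens crystallin and exocrine pancreas transcripts were lower together. Genes that rose and took a larger part of the TPM total are argued against, since after TMM-type rescaling the 3 list medians still lay between -0.59 and -0.42, and after quantile normalization at -0.24 for muscle, -0.51 for lens and -0.59 for pancreas. A smaller share of muscle or of lens as the whole cause needs 1 common fall only if each tissue's members are expressed there alone. That was not tested. The members' folds differed by more than their errors (weighted squared deviations per degree of freedom of 21.1 for muscle and 8.15 for lens). These errors rest on a spread that may be technical, so the values cannot decide against a smaller share, which stays open. For the exocrine pancreas the same measure was 2.99, between the bounds of 2 and 3 set for the test. A smaller pancreas thus cannot be told apart from regulation within it. Slower development of exposed larvae may contribute and stays open: the cartilage list had a median 0.046 above that of all genes and the myelin list a difference of -0.016, both too close to 0 to decide.

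Macrophage marker transcripts were higher. More macrophages as the whole cause would raise the markers alike only if macrophages alone expressed them. The test left out apoeb, tspan36, csf1ra and csf1rb, which other cells express too. On log2(TPM + 0.1), which understates low genes less, the folds of the 19 members left differed by more than their errors. The weighted squared deviations per degree of freedom came to 25.8, as with 0.74 for mpeg1.1 against 5.26 for mpeg1.2. Expression of the 19 members in other cells would also make the rises unequal. The value therefore cannot decide against more macrophages. Reads moved between paralogs are argued against, because the summed TPM of mpeg1.1 with mpeg1.2, ctss2.1 with ctss2.2 and grn1 with grn2 reached at least 5.51 times the control level. More macrophages, their activation by the particles and expression of these genes in other cells stay open, since RNA of whole larvae carries no cell of origin. Activation and expression in other cells are untested hypotheses.

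The embryonic beta globin genes hbbe1.1, hbbe1.2 and hbbe1.3 went opposite ways. A change in erythrocyte number alone would not move these genes opposite ways, and hbbe1.2 and hbbe1.1 differed by 3.31 in log2 fold change. That difference is the pattern itself and no separate test. It does not exclude a change in erythrocyte number beside another cause. Reads moved between these near copies cannot be told apart from regulation, because how the counting divided shared reads is not given. The TPM gained by hbbe1.2 and hbbe1.3 came to 61.1% of that lost by hbbe1.1, and the sum of the 3 genes went from 784 ± 3.06 to 620 ± 8.80 TPM (SD, n = 2). Different parental alleles in the pools of larvae, and an effect of exposure on globin switching, are open and untested.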
